A study of Mus musculus with 24 samples.

How the data were processed

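RNA was measured by poly-A selected, paired-end sequencing of snap-frozen brain from 24 mice, per the labels' protocols. The knockouts lack the LDL receptor, which clears cholesterol-carrying lipoproteins from blood, and on a high-fat diet they serve as a model of raised blood cholesterol and atherosclerosis. Adropin is a small secreted peptide made from the gene Enho. Per the labels, 7 mice were LDL receptor knockouts on a high-fat diet for 3 months (LDLRKO HFD), 8 were knockouts that also carried the adropin transgene on the same diet (AdrTG;LDLRKO HFD), and 9 were wild types on chow (WT chow). The replicates are taken as separate mice, since each label carries its own animal number. For 3 LDLRKO HFD libraries the sex-linked genes described below leave this open. All 24 labels give the sex as male, while the treatment protocol speaks of male and female offspring on the high-fat diet. The brain region, the strand setting of the counting and the genome build of the alignment are not given in the sources used here.

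The deposited table holds whole-number counts per Ensembl gene, 1 column per library and not normalized. Per the submitters' processing notes, the tools were bcl2fastq, STAR, Subread, featureCounts, Salmon, edgeR and limma. The table has 40757 entries for 40481 genes, and 276 entries that repeat a gene with the same counts were dropped, after checking that they were identical. Of the 40481 genes, 31320 had at least 1 read. The authors' table of counts scaled to library size was not used here, since the counts hold the same measurement. Total counts per library ran from 39.2 to 68.0 M (mega) with a median of 48.1 M, from 41.9 to 68.0 M in WT chow, 41.0 to 65.1 M in LDLRKO HFD and 39.2 to 59.2 M in AdrTG;LDLRKO HFD. Gm42418, a predicted gene that overlaps ribosomal RNA sequence, held 1.09% to 3.83% of the counts of a library. Mitochondrial protein-coding genes held 2.77% to 3.90%. Counting error limits genes below about 1 CPM (counts scaled to library size), and the protocol names no molecular identifiers.

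Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter by group, a robust quasi-likelihood fit of a model with 1 mean per group over all 24 libraries, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The filter left 18616 genes, and the biological coefficient of variation was 13.8%. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over mice, and log2 fold changes carry the standard error of the fit. The comparisons were AdrTG;LDLRKO HFD against LDLRKO HFD, LDLRKO HFD against WT chow, and AdrTG;LDLRKO HFD against WT chow. Genotype, diet and cohort change together between the wild types and the other groups, and no batch is given in the labels. Age may differ too, since the titles bound it only for the wild types. Replicates were compared before they were averaged. In the 85 pairs of libraries within groups, the chi-square statistic per degree of freedom ran from 9.40 to 83.6 and 0 pairs were identical, so every library was kept as its own replicate.

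Lists of genes for metabolic and immune processes, brain cell types and brain regions were written before the data were examined, as were the samples, the tests and the rule for naming genes. Of 958 symbols in 46 lists, 952 were found in the table. The list of sex chromosome genes was not tested as a group, which left 45 lists. Each was tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the 45 lists, and repeated with a correlation estimated for each list and with fry. Camera compares a list with all other genes, while fry tests whether the members move on balance in a single direction. Cell type and region lists were also scored per library as the mean log2 CPM of their members and compared between groups with exact, two-sided permutation tests in scipy 1.17.1, adjusted over 22 lists. The same test on the 23 process lists was added after the data were seen.

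Genes are named by this rule, set for each comparison. Enho and Ldlr are always named. Called genes with at least 1 CPM and a symbol that is neither predicted nor sex-linked follow, up to 8 with the largest rise and 8 with the largest fall. The members with the smallest p, up to 3, of up to 8 lists with the smallest camera p are added, and the 10 genes with the smallest p where fewer than 10 passed. Genes called in opposite directions in the first 2 comparisons complete the set. Genes named outside this rule were chosen after their values were seen, and the text says so. Gene positions were taken from GENCODE M21 on GRCm 38 by Ensembl identifier, which matched 40254 of 40481 genes.

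The test of genes was run on simulated counts drawn from the means, dispersions and library sizes of these libraries, with known changes in a set of genes. In the comparison of the transgenic knockouts with the knockouts, run on 18616 genes, 25.4% of genes changed by a log2 of 0.25 were recovered, 68.7% at 0.5 and 87.9% at 1. For the knockouts against the wild types the shares were 32.8%, 61.2% and 81.8%, and for the transgenic knockouts against the wild types 25.4%, 71.6% and 83.3%. Of the 128, 123 and 125 genes called in these simulations, 7, 6 and 5 were unchanged ones. The simulated counts were drawn gene by gene, without the differences among libraries that many genes share in the real data. The shares of recovered and unchanged genes may therefore look better than in the real libraries. Alternatives were other normalizations, filters, thresholds and tests (DESeq2 1.42.0, limma voom with quality weights), surrogate variables from sva 3.50.0, covariates for tissue makeup, fits of only the groups compared and fits without each library in turn. Random splits of the libraries, 100 per comparison, gave the results that other groupings yield. Figures were drawn with matplotlib 3.10.9.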

Results

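The study asked what extra adropin does in the brain of mice that lack the LDL receptor and eat a high-fat diet, a model of raised blood cholesterol. Poly-A RNA was sequenced from 24 brain samples, each labelled with its own animal number. There were 9 wild types on chow (WT chow), 7 knockouts on the high-fat diet for 3 months (LDLRKO HFD, the knockouts below) and 8 knockouts with the adropin transgene on that diet (AdrTG;LDLRKO HFD, the transgenic knockouts). Libraries are named by a letter for the group (W for WT chow, K for the knockouts, T for the transgenic knockouts) and the animal number of the label, as in K590. Libraries held 39.2 M to 68.02 M counts (M, mega), and 18616 genes had enough reads to test. Any pair of libraries correlated at 0.974 to 0.993 over log2 CPM of these genes. The first principal component carried 21.6% of the variance and followed markers of brain regions. Across the 24 libraries it correlated at r = 0.90 with the cortex layer list and at -0.87 with the hypothalamus list, as a description of the libraries with no test.

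The genes behind the model were read first in every library. Enho, which encodes adropin (chromosome 4, 41638144 to 41640324, minus strand), stood at 41.7 ± 1.77 CPM in WT chow (n = 9), 42.0 ± 1.05 CPM in the knockouts (n = 7) and 41.9 ± 4.63 CPM in the transgenic knockouts (n = 8). Its log2 fold change was -0.00 (SE 0.05, adjusted p = 0.996) between the transgenic knockouts and the knockouts, 0.01 (adjusted p = 0.962) between the knockouts and the wild types and 0.01 (adjusted p = 0.9991) between the transgenic knockouts and the wild types. Libraries ran from 33.7 to 50.2 CPM in the transgenic knockouts and from 40.8 to 44.1 CPM in the knockouts. The sequence of the transgene is not given in the sources used here, so that reads from it may not be counted under Enho, and its level does not check the transgene label. Ldlr, the receptor gene (chromosome 9, 21723483 to 21749919, plus strand), stood at 31.6 ± 3.48 CPM in WT chow, 26.6 ± 2.63 CPM in the knockouts and 25.3 ± 2.27 CPM in the transgenic knockouts. It fell in the transgenic knockouts against the wild types (log2 fold change -0.32, SE 0.07, adjusted p = 0.0337), while the change of -0.25 (SE 0.07, adjusted p = 0.270) in the knockouts did not pass. The part of Ldlr that was deleted is not given in the sources used here, and a count over the whole gene does not check the genotype.

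Sex-linked genes were not alike in all libraries labelled male. Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254, minus strand), reached 210, 414 and 365 CPM in K636, K730 and K731. It was at 4.96 CPM in K590 and 6.67 CPM in K732, and at most 0.731 CPM in the wild types and 0.642 CPM in the transgenic knockouts. Y-linked Ddx3y, an RNA helicase gene, stood at 22.9, 16.0 and 14.9 CPM in K636, K730 and K731 and between 41 and 49.6 CPM in the other 4 knockout libraries. Over Ddx3y, Eif2s3y, Kdm5d and Uty, the Y-linked level in these 3 libraries averaged 54.9%, 31.95% and 38.04% of the mean of the other 4. Counts of called genes and passing lists in the comparisons with the knockouts are therefore also given without these 3 libraries, a choice made after seeing the data. These 3 are called the libraries with Xist below, though K590 and K732 also held more Xist than any wild type or transgenic knockout.

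**Figure D1:**
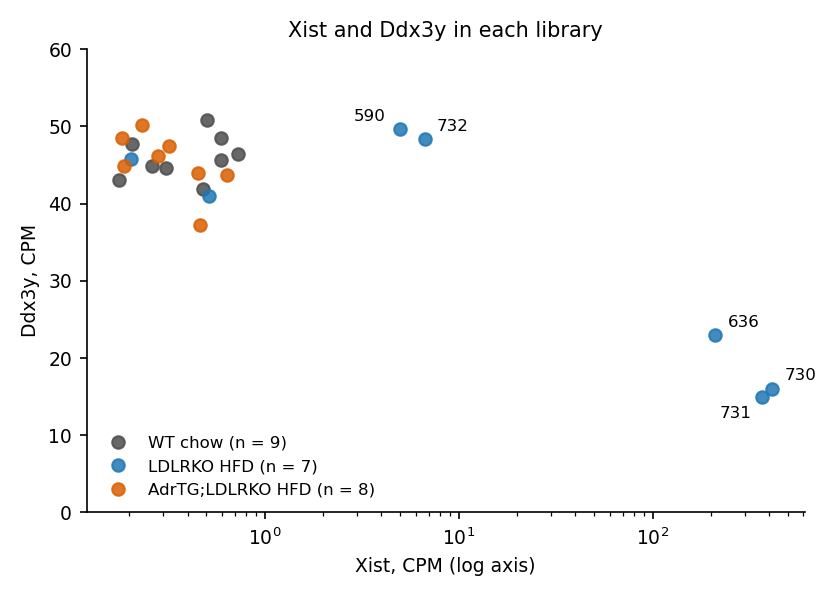
Xist (CPM, log axis) against the Y-linked gene Ddx3y (CPM) in each of the 24 libraries, coloured by group, with the number of each knockout library above 1 CPM of Xist. K636, K730 and K731 combine Xist at 210 to 414 CPM with Ddx3y at 14.9 to 22.9 CPM.

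The comparison of the transgenic knockouts with the knockouts asks what the transgene changed under the same diet. The 3 genes that rose were neighbours on chromosome 2, and the only gene that fell was Xist. The long noncoding RNA Gm14005 (128178319 to 128502765, minus strand) rose 18.3-fold, from 0.264 ± 0.157 CPM (n = 7) to 4.83 ± 0.530 CPM (n = 8), a log2 fold change of 4.19 (SE 0.34, adjusted p = 8.55e-08). Gm14010, annotated on the other strand inside the span of Gm14005 (128423654 to 128424565), rose from 0.0259 ± 0.0261 to 1.39 ± 0.661 CPM (log2 fold change 5.52, SE 0.54, adjusted p = 6.6e-07). Gm14006, a processed pseudogene (128557254 to 128558234), rose from 0.0114 ± 0.0199 to 1.09 ± 0.604 CPM (log2 fold change 6.31, SE 0.55, adjusted p = 9.83e-08). In all 3 genes each of the 8 transgenic knockouts lay above each of the 7 knockouts, and the wild types were as low as the knockouts, at 0.171, 0.0294 and 0.00381 CPM for Gm14005, Gm14010 and Gm14006. Without a stated strand the reads of Gm14010 and Gm14005 cannot be told apart, and a pseudogene can take reads from its parent gene. These 3 genes were named after their values were seen, since they fall outside the naming rule.

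Xist fell by 8.68 on the log2 scale (SE 1.35, adjusted p = 0.00980), from 143 ± 185 to 0.345 ± 0.161 CPM, and this call rests on K636, K730 and K731. Without these 3 libraries the Xist adjusted p was 0.156, and it was 0.6001 with limma voom and quality weights, 0.502 with only both groups in the fit, 0.148 with the animal-number series as a covariate and 0.316 with 2 surrogate variables. Its log2 fold change was -3.15 without the 3 libraries, -5.70 with limma voom and -9.27 with a cortex layer covariate. Gm14005, Gm14006 and Gm14010 were the 3 genes still called without the 3 libraries, and Gm14006 stood at 6.95 without K731.

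**Figure D2:**
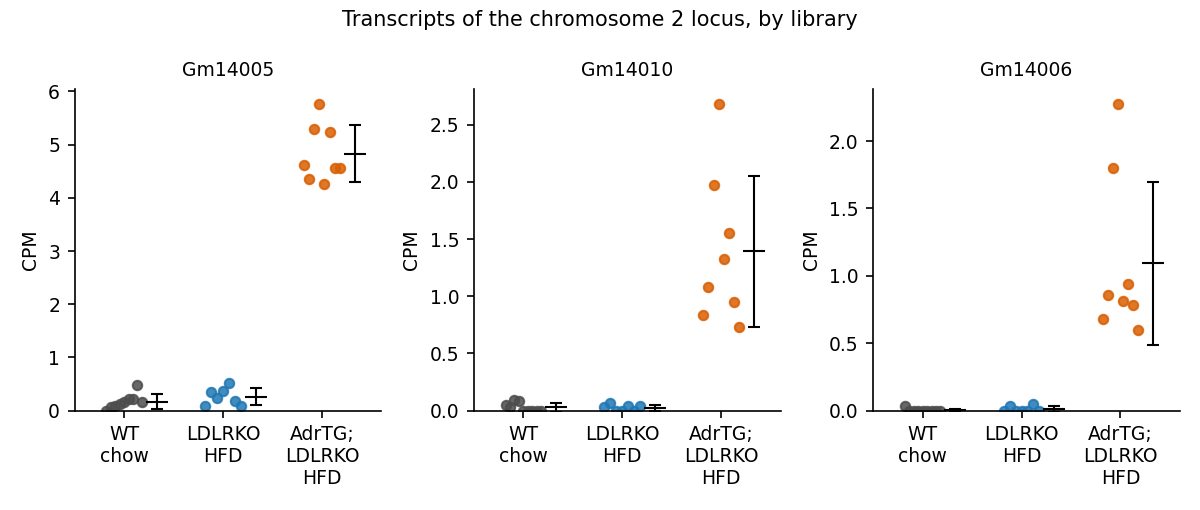
CPM of Gm14005, Gm14010 and Gm14006 in each library, by group (points), with the mean and SD of each group (bars). All 8 AdrTG;LDLRKO HFD libraries lie above all libraries of the other groups in each panel.

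No clear rise was seen in the protein-coding genes around these transcripts. Within 1 Mb of the 3 genes, 43 genes were tested, these 3 included, and 34 of them were protein-coding. Of these 34, 0 were higher in the transgenic knockouts at an unadjusted p under 0.05 in edgeR. Bcl2l11, a gene of cell death nearby that was picked after its value was seen, stood at 6.24 CPM against 5.81 CPM (log2 fold change 0.10, adjusted p = 0.679).

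Beyond these 4 genes the largest signals did not pass. Kdm5b, a histone demethylase gene, was at 64.9 ± 3.00 against 57.9 ± 1.90 CPM (log2 fold change 0.16, SE 0.03, adjusted p = 0.226), with 7 of 8 transgenic knockouts above every knockout, and DESeq2 called it (adjusted p = 0.0166). Gzmm, which encodes a granzyme of cytotoxic lymphocytes, was at 1.59 ± 0.188 against 2.24 ± 0.294 CPM (log2 fold change -0.50, adjusted p = 0.424). The ubiquitin ligase gene Mid1 (-0.63), the Polycomb component Rybp (0.24), the serotonin receptor gene Htr5b (0.99), the RNA-binding protein gene Dazap1 (-0.15), the lipoprotein receptor gene Vldlr (0.18), March1 (0.23), Klhdc4 (-0.17) and the chemokine receptor gene Ccr5 (0.37) all had an adjusted p of 0.551. For Gzmm and Dazap1 all 8 transgenic knockouts lay below every knockout. Vldlr passed when adjusted over the list alone, as the only member of the cholesterol transport list to do so. DESeq2 called 5 genes in this comparison. With edgeR, 1603 genes had an unadjusted p under 0.05, where 930.8 would be expected by chance for independent genes. Of 100 random splits of the same libraries, the real split included, 14 gave at least as many, and the highest other gave 4259.

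Of the 45 gene lists, 9 passed camera in this comparison, 8 lower and 1 higher in the transgenic knockouts. All 9 calls were lost with an estimated correlation between members (adjusted p = 0.968 for each). The shifts were small and spread over members, none of which was called. Nuclear genes of oxidative phosphorylation, which makes most cellular ATP, were lower in 71 of 74 members with a median log2 fold change of -0.04 (adjusted p = 8.32e-07), among them Atp5d (-0.07), Cox5a (-0.13) and Cox6a1 (-0.09). Ribosomal protein genes were lower in 69 of 74, with a median of -0.04 (-0.02 without T589; adjusted p = 8.49e-05), for example Rpl12 (-0.09), Rpl13a (-0.08) and Rps9 (-0.07). The interferon response list, genes induced by antiviral signalling, was lower in 21 of 26 with a median of -0.10 (adjusted p = 0.00161), with Gbp2 at -0.43, Ifit3 at -0.24 and Xaf1 at -0.27. Antigen presentation genes were lower in 14 of 17 (median -0.10, adjusted p = 0.0140), with Psmb9 at -0.40, H2-Q4 at -0.32 and H2-K1 at -0.20, genes whose family members can share reads. Myelin genes of oligodendrocytes were lower in 22 of 23 (median -0.17, -0.09 without K590; adjusted p = 0.00316), with Olig2 at -0.13, Gjb1 at -0.30 and Gjc2 at -0.30. Red blood cell genes were lower in 7 of 9 (median -0.33, adjusted p = 0.00333), including the near-identical haemoglobin genes Hba-a1 (-0.38) and Hba-a2 (-0.42) and Hbb-bs (-0.42). Endothelial markers (Tie1 -0.14, Cldn5 -0.10, Esam -0.16) were lower in 16 of 18 (adjusted p = 0.0227) and mitochondrially encoded genes in 13 of 13 (adjusted p = 0.0355). Microglia markers were higher in 17 of 20 (median 0.06, adjusted p = 0.0140), with Cx3cr1 at 0.14, Ly86 at 0.17 and Itgam at 0.12. Over the 24 fits without 1 library the medians were -0.07 to -0.02 for oxidative phosphorylation (nearest 0 without T635), -0.07 to -0.02 for ribosomal proteins, -0.15 to -0.08 for interferon, -0.13 to -0.08 for antigen presentation, -0.23 to -0.09 for myelin, -0.48 to -0.18 for red blood cells (nearest 0 without T727) and 0.03 (without K590) to 0.09 (without K592) for microglia.

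With an estimated correlation 0 lists passed camera (adjusted p = 0.968 for all 9 lists above), with 2 at an unadjusted p under 0.05, and with fry 0 passed, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.406. When lists were scored per library, the interferon score differed by -0.13, with 8 of 8 transgenic knockouts below the knockout mean, at an exact permutation p of 0.00995 that did not pass over 23 process lists (adjusted p = 0.229). Over the 22 cell type and region lists, 0 passed the exact permutation test, with 1 at p under 0.05, red blood cells (adjusted p = 0.579). Without the 3 libraries with Xist 7 lists passed, 5 of them among the 9, and the calls of antigen presentation (median -0.08 from -0.10, adjusted p = 0.135), red blood cells (-0.12 from -0.33, 0.130), microglia (0.04 from 0.06, 0.135) and mitochondrially encoded genes (-0.02 from -0.07, 0.809) ended. The antigen presentation median thus hardly moved, and its call ended with fewer libraries in the fit. With a cortex layer covariate, chosen after seeing the data, those of endothelial markers (median -0.03 from -0.07, adjusted p = 0.336), microglia (0.04 from 0.06, 0.174) and myelin (-0.02 from -0.17, 0.483) ended. Leaving out T589 reduced the passing lists from 9 to 5 and ended the calls of ribosomal proteins (median -0.02 from -0.04, adjusted p = 0.332) and antigen presentation (-0.10 in both, adjusted p = 0.0524). Calls also ended for myelin without K590 or T727 (medians -0.11 to -0.09, adjusted p 0.0798 to 0.220) and for microglia without K590 or K732 or T583 or T733 (medians 0.03 to 0.05, adjusted p 0.0666 or more). The endothelial call ended without K590 or K592 or T589, T727 or T733 (medians -0.07 to -0.03 from -0.07, adjusted p 0.0781 to 0.221), and that of mitochondrially encoded genes without K592, K636, K730, K731 or K732 or T589, T591 or T728 (medians -0.07 to -0.05 from -0.07, adjusted p 0.0620 to 0.378).

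The comparison of the knockouts with the wild types joins genotype, diet and cohort, and age may differ as well. The clearest change was a block of 9 neighbouring genes on chromosome 19 that rose together, between 57323193 and 58777534. Fam160b1 rose from 40.95 ± 2.24 CPM (n = 9) to 74.0 ± 12.1 CPM (n = 7; log2 fold change 0.85, SE 0.07, adjusted p = 2.04e-08). Atrnl1, which encodes a transmembrane protein related to attractin, rose from 136 ± 9.94 to 260 ± 40.2 CPM (log2 fold change 0.94, SE 0.08, adjusted p = 4.15e-08). Trub1, a pseudouridine synthase gene, rose by 0.76 (SE 0.10, from 22.8 to 38.7 CPM), Gfra1, a receptor gene for the neurotrophic factor GDNF, by 0.84 (SE 0.15, from 39.5 to 70.7 CPM) and the noncoding B230217O12Rik by 0.84 (SE 0.08). Pancreatic lipase, Pnlip, a digestive enzyme gene, rose 10.8-fold, from 0.659 ± 0.344 to 7.15 ± 2.70 CPM (log2 fold change 3.43, SE 0.27, adjusted p = 3.57e-08). Its relatives were near 0 in the wild types and detected in the knockouts, Pnliprp2 at 0.0614 and 0.753 CPM, Pnliprp1 at 0.0106 and 0.511 CPM and the pseudogene 1810018F18Rik at 0.00395 and 1.26 CPM. In each of these 9 genes except Gfra1, all 7 knockouts lay above all 9 wild types, and for Gfra1 5 of 7 did. The lipase relatives and the overlapping pair of Fam160b1 and B230217O12Rik can share reads. B230217O12Rik, Pnliprp1, Pnliprp2 and 1810018F18Rik were named after their values were seen. Without the 3 libraries with Xist, 8 of the 9 stayed called, and Gfra1 had a log2 fold change of 0.83 (SE 0.17, adjusted p = 0.108).

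**Figure D3:**
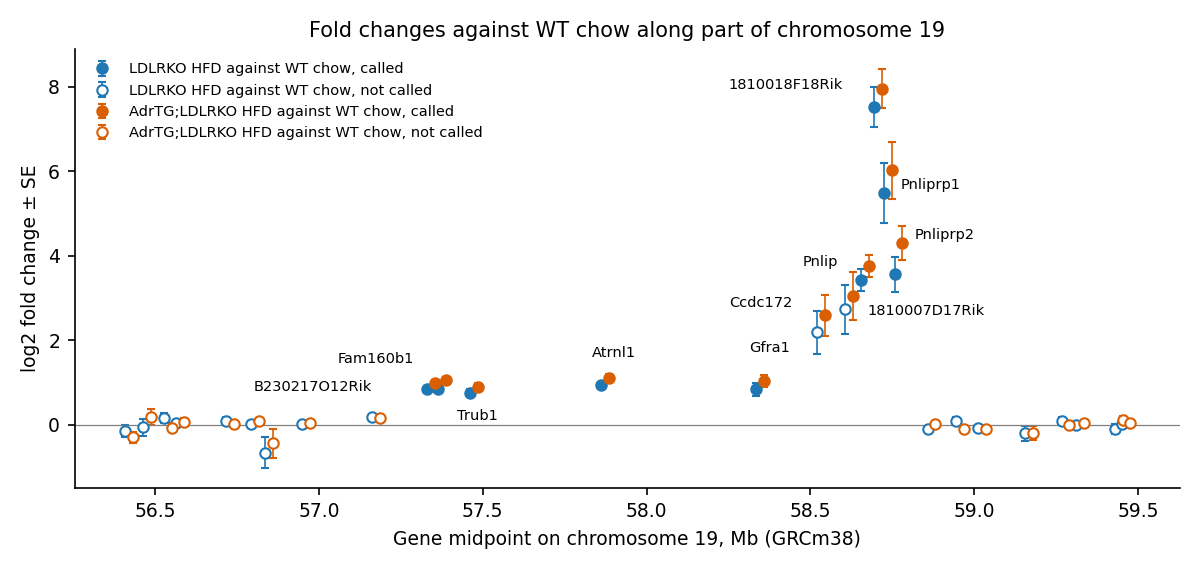
Log2 fold changes against WT chow (points, with SE) of the 28 genes tested in this part of chromosome 19, by gene midpoint (Mb, GRCm38), for both knockout groups; filled points were called. Called genes lie between 57323193 and 58777534, and the fitted values of genes near 0 in WT chow, such as 1810018F18Rik and Pnliprp1, depend on the prior count of the fit.

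Outside this block, 20 genes were called in the knockouts against the wild types, 17 higher and 3 lower. The microglia list as a whole did not pass (median -0.00, camera's adjusted p = 0.746), with a mean log2 CPM of 4.47 in both groups. Lyz2, a lysozyme gene of macrophages, rose from 5.82 ± 0.796 to 8.47 ± 1.33 CPM (log2 fold change 0.54, SE 0.10, adjusted p = 0.0136). Itgax, which encodes the integrin CD11c of activated microglia and dendritic cells, rose from 0.275 ± 0.111 to 0.700 ± 0.154 CPM (1.34, SE 0.26, adjusted p = 0.0163). The interferon regulator Irf7 rose from 2.20 ± 0.233 to 3.34 ± 0.762 CPM (0.61, SE 0.13, adjusted p = 0.0398) and Slfn2, an interferon-induced gene of the Schlafen family, from 1.18 ± 0.207 to 2.16 ± 0.428 CPM (0.87, SE 0.17, adjusted p = 0.0197). Crybb1, a crystallin gene that microglia express, rose from 4.15 ± 0.611 to 6.95 ± 1.34 CPM (0.74, SE 0.12, adjusted p = 0.00124), with all 7 knockouts above all 9 wild types. Mpeg1, a pore-forming protein gene of macrophages, fell by 0.37 on the log2 scale (SE 0.07, adjusted p = 0.00805), with all 7 knockouts below all wild types. Rnf145, a ubiquitin ligase gene of the endoplasmic reticulum, fell by 0.21 (SE 0.03, adjusted p = 0.00098), and the X-linked Mid1 rose by 0.74 (SE 0.15, adjusted p = 0.0263). Named after their values were seen, the microglial genes Lag3 (0.49) and Olfml3 (0.32), the antiviral gene Oas2 (1.22), Slc41a3 (0.55), Zfp846 (0.37), Adipor2, an adiponectin receptor gene (0.33), Rasd2 (0.36), Kremen1 (0.25) and Zfp827 (0.17) also rose, as did Xist (8.37), and 2310022B05Rik (-0.28) fell. Trem2 (0.23, adjusted p = 0.0927), Ifitm3 (0.48, adjusted p = 0.0888) and Ifit1 (0.55, adjusted p = 0.1404) did not pass in edgeR, and DESeq2 called all 3.

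In total 29 genes were called in the knockouts against the wild types, 26 higher and 3 lower, and 1811 had an unadjusted p under 0.05 in edgeR, a count reached in 8 of 100 random splits, the real split included. Without the 3 libraries with Xist 11 genes were called, 10 of them among the 29, namely 8 of the block with Slc41a3 and Zfp846. The other was Adamts16, a metalloprotease gene (-1.03, adjusted p = 0.0425). Calls then ended for Crybb1 (0.58, adjusted p = 0.128), Lyz2 (0.47, 0.221), Itgax (1.47, 0.0696), Irf7 (0.69, 0.128), Slfn2 (0.79, 0.254), Mpeg1 (-0.30, 0.248), Mid1 (0.70, 0.256) and Rnf145 (-0.20, 0.0696), given as log2 fold change and adjusted p. All 35 choices of 4 of the 7 knockout libraries called 11 to 26 genes with a median of 17. The choice without K636, K730 and K731 gave the lowest count. The Xist call ended without these libraries (2.84, 0.0696) and with limma voom (5.42, 0.597). A cortex layer covariate ended the calls of Itgax (1.27, 0.0752), Irf7 (0.57, 0.138), Mid1 (0.72, 0.0617) and Slfn2 (0.78, 0.0919), with folds near those without it. The calls of Itgax with 2 surrogate variables (0.0638) and of Mid1 in a fit of only both groups (0.0819) ended too, given as adjusted p. Leaving out 1 library ended the call of Itgax (without K732, adjusted p = 0.0528), Lyz2 (without K730, 0.0506), Slfn2 (without W8 or W9 or K592 or K731, 0.0533 to 0.0790) and Mid1 (without W3, W5, W8 or W12 or K636, K730 or K732, 0.0513 to 0.101). Irf7 lost its call in 14 such fits, without W3, W4, W5, W6, W8, W9 or W10, K590, K592, K634, K730 or K731, or T589 or T728 (0.0524 to 0.146), and Ifitm3 gained a call without W12 (0.0449) or T726 (0.00292). Where these calls ended the folds of Itgax (1.28), Lyz2 (0.47), Slfn2 (0.79 to 0.86), Mid1 (0.64 to 0.72) and Irf7 (0.53 to 0.62) lay near those of all libraries.

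**Figure D4:**
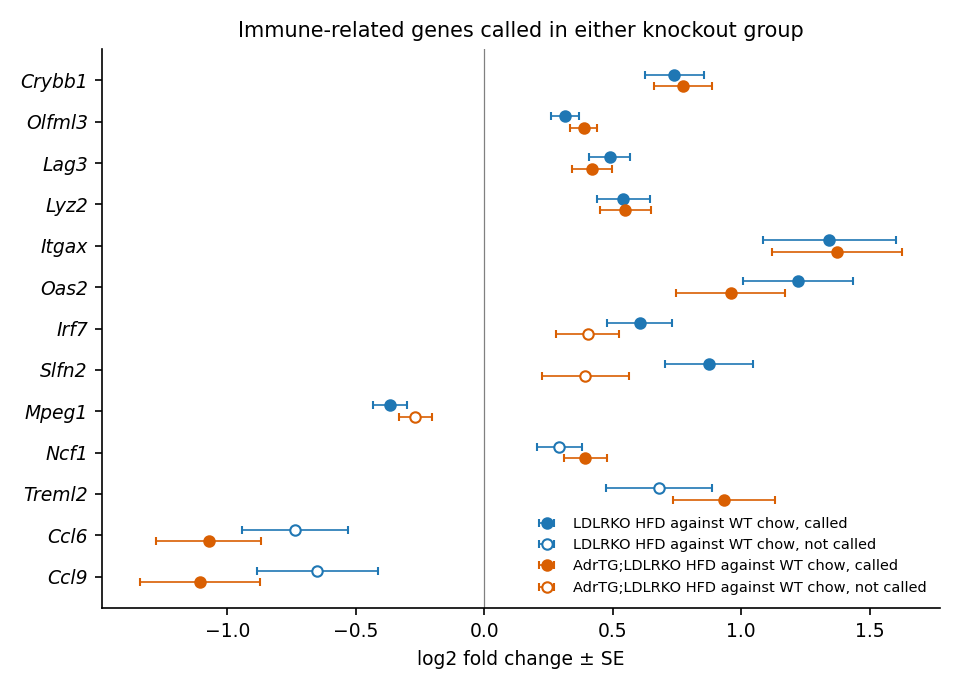
Log2 fold changes against WT chow (points, with SE) in both knockout groups for 13 immune-related genes called in at least 1 of these comparisons, picked after their values were seen; filled points were called. Itgax lies at 1.34 and 1.37, Lyz2 at 0.54 and 0.55 and Mpeg1 at -0.37 in LDLRKO HFD.

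Among the lists, the interferon response rose most clearly in the knockouts. All 26 measured members were higher than in the wild types, with a median log2 fold change of 0.27 and camera's adjusted p = 2.69e-13. It also passed with an estimated correlation (adjusted p = 0.00441) and with fry (adjusted p = 0.000141), though 7 of 100 random splits of these libraries, the real split included, passed at least 1 list with an estimated correlation. Irf7 was the only member called over all genes, and 7 members passed when adjusted over the list alone. Its mean log2 CPM was 1.79 ± 0.07 in the knockouts and 1.48 ± 0.12 in the wild types, with 7 of 7 knockouts above the wild-type mean (exact permutation p = 0.000524, adjusted p = 0.00603). Antigen presentation genes rose in camera too (16 of 17 higher, median 0.25, adjusted p = 4.78e-07; adjusted p = 0.0737 with an estimated correlation, 0.0104 with fry), with B2m at 0.28, H2-K1 at 0.28 and H2-Q4 at 0.36, none of them called over all genes, and 6 members passing when adjusted over the list alone. Their score was higher by 0.23 with an exact permutation adjusted p of 0.00603. Glucocorticoid target genes, induced by stress hormones, were higher in 18 of 22 (median 0.13, adjusted p = 0.00222; adjusted p = 0.563 with an estimated correlation), with Nfkbia at 0.32, Sgk1 at 0.37 and Lcn2 at 2.74 (SE 0.93), none of them called (adjusted p = 0.200, 0.386 and 0.394). Their score was higher by 0.22 (exact permutation adjusted p = 0.0389). Without the 3 libraries with Xist these scores were higher by 0.32 (interferon), 0.19 (antigen presentation) and 0.14 (glucocorticoid), and 0 of 23 process lists passed the exact permutation test, with 5 at p under 0.05 and adjusted p of 0.0965, 0.0965 and 0.167. With only 4 knockouts left, few regroupings exist, which limits how small an exact p can be. The end of these calls therefore does not show that the shifts were lost.

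**Figure D5:**
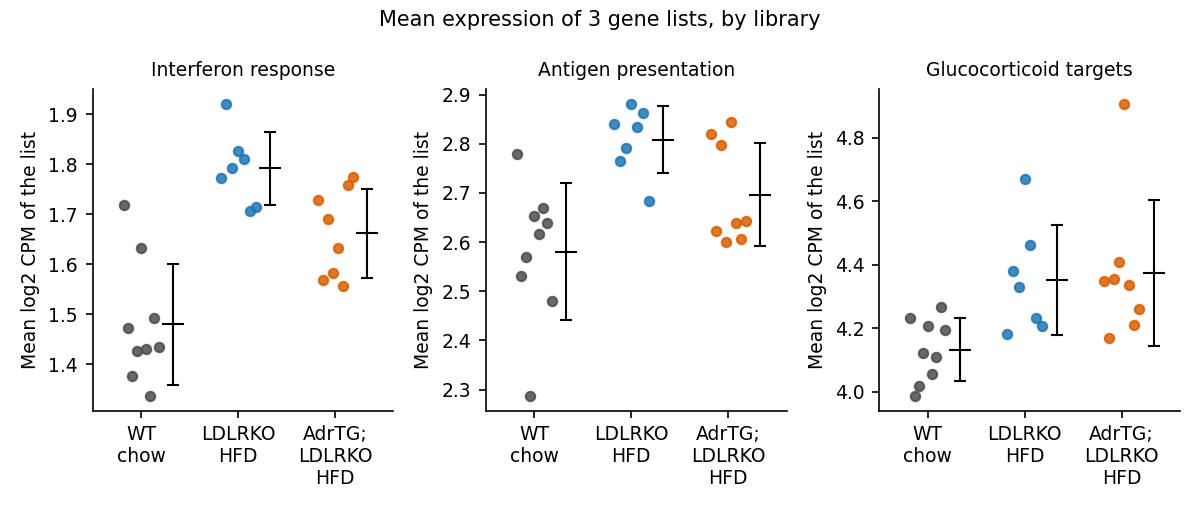
Mean log2 CPM of the members of 3 gene lists in each library, by group (points), with the mean and SD of each group (bars). The interferon score averages 1.48 in WT chow and 1.79 in LDLRKO HFD.

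Both lipid synthesis lists were lower in the knockouts in camera with the preset correlation. Neither passed with an estimated correlation or with fry (fry's adjusted p = 0.183 for cholesterol and 0.376 for fatty acid synthesis). In the cholesterol synthesis list, which holds targets of the sterol sensor SREBP2, 24 of 26 were lower with a median of -0.09 (adjusted p = 7.65e-05; adjusted p = 0.423 with an estimated correlation), among them Ldlr (-0.25), Fdft1 (-0.10) and Sqle (-0.17), and the only member to pass when adjusted over the list alone was Ldlr, the gene targeted in these mice. Fatty acid synthesis genes were lower in 14 of 18 (median -0.07, adjusted p = 0.0108; 0.762 with an estimated correlation), with 2 passing when adjusted over the list alone. Genes of disease-associated microglia, a state seen near amyloid plaques, were higher in 12 of 21 (median 0.08, adjusted p = 0.00433; 0.340 with an estimated correlation), and Lyz2 and Itgax were called. Adjusted over the list alone, 5 of these genes were higher and 1 lower. Complement and inflammation genes were higher in 13 of 20 (adjusted p = 0.0279; 0.423 with an estimated correlation) and heat shock and unfolded protein genes in 25 of 32 (0.00139; 0.762), with Hspb1 at 0.36, Herpud1 at 0.18 and Pdia3 at 0.10. Nuclear oxidative phosphorylation genes were higher in 63 of 74 at a median of 0.02 (0.0115; 0.826). Among cell types and regions, endothelial markers were higher in 15 of 18 (1.20e-05; 0.423), with Cdh5 at 0.19, Ly6a at 0.47 and Abcb1a at 0.19. Myelin genes were higher in 23 of 23 (0.00139; 0.826; Olig2 0.21, Gjb1 0.24, Gjc2 0.27), red blood cell genes in 7 of 9 (0.00433; 0.423) and cortex layer markers in 13 of 19 (0.0279; 0.762), while hippocampus markers were lower in 12 of 18 (0.0133; 0.762).

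That makes 14 lists that passed in the knockouts against the wild types, 11 higher and 3 lower, and 1 passed with an estimated correlation. The exact permutation test of the 22 cell type and region scores passed 0, with 3 at p under 0.05 and a smallest adjusted p of 0.154, for endothelial markers. Without the 3 libraries with Xist the camera calls of red blood cells (median 0.14 from 0.33, adjusted p = 0.162), complement (0.02 from 0.05, 0.162), fatty acid synthesis (-0.03 from -0.07, 0.459), glucocorticoid targets (0.07 from 0.13, 0.222), oxidative phosphorylation (0.02 in both, 0.155) and heat shock (0.04 from 0.07, 0.0963) ended. That left 11 passing lists, 8 of them among the 14. With a cortex layer covariate the call of hippocampus ended (median -0.09 from -0.10, adjusted p = 0.257) and the medians of myelin (from 0.11 to -0.0553) and oxidative phosphorylation (from 0.02 to -0.00560) turned direction. The median of cortex layers went from 0.12 to 0.0107, which follows from the covariate, the score of that list. Leaving out 1 library ended the call of complement (W6, W9, W11 or W12 or K592, K636 or K731; medians 0.02 to 0.06 from 0.05, adjusted p 0.0506 to 0.120), cortex layers (W3, W4 or W5 or K590 or K634; 0.08 to 0.15 from 0.12, 0.0566 to 0.0944) and fatty acid synthesis (W3 or K731; -0.07 to -0.06 from -0.07, 0.0589 to 0.0638). It also ended those of hippocampus (W3 or W4 or K592; -0.13 to -0.09 from -0.10, 0.0533 to 0.0807), myelin (K590; 0.03 from 0.11, 0.0839) and oxidative phosphorylation (W4 or K730; 0.02 in all, 0.0566 to 0.0861). The complement median was lowest without K636 (0.02) and 0.03 without K592. Without 1 library the medians were 0.01 (without K636) to 0.13 for disease-associated microglia, 0.08 (without K636) to 0.16 for glucocorticoid targets, 0.03 to 0.22 for myelin, -0.24 to -0.08 for hippocampus and 0.23 to 0.32 for interferon.

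The transgenic knockouts were compared with the wild types to ask which of these differences were present with the transgene. The chromosome 19 block rose here too, with Fam160b1 at a log2 fold change of 1.06 (SE 0.07, 85.5 ± 4.36 against 40.95 ± 2.24 CPM, n = 8 and 9, adjusted p = 6.8e-11), Atrnl1 at 1.12 (SE 0.08, 295 ± 31.5 CPM), Trub1 at 0.90 (SE 0.09), Gfra1 at 1.04 (SE 0.15), B230217O12Rik at 0.99 (SE 0.08) and Pnlip 13.5-fold higher at 8.95 ± 1.23 CPM. Pnliprp2 was at 1.25 CPM, Pnliprp1 at 0.733 CPM and 1810018F18Rik at 1.70 CPM, and Ccdc172 (2.596) and 1810007D17Rik (3.05) in the same block were called as well. Gm14005, Gm14006 and Gm14010 rose as in the first comparison, with Gm14005 at 4.81. Crybb1 (0.77, adjusted p = 0.000281), Lyz2 (0.55), Itgax (1.37), Lag3 (0.42), Olfml3 (0.39) and Oas2 (0.96) rose. Slc38a5, a glutamine transporter gene, rose from 2.24 ± 0.487 to 4.27 ± 1.87 CPM (0.93, SE 0.18, adjusted p = 0.0170), and the noncoding Fbxl12os by 0.66 (adjusted p = 0.0342). Lower were Cirbp, a cold-inducible RNA-binding protein gene, at 45.7 ± 4.97 against 55.9 ± 3.85 CPM (-0.29, SE 0.06, adjusted p = 0.0216), Accs (-0.43, adjusted p = 0.0342), Arrdc1 (-0.33, adjusted p = 0.0342), Rnf145 (-0.14, adjusted p = 0.0431) and Ldlr as above. Named after their values were seen, the chemokine genes Ccl6 (-1.07) and Ccl9 (-1.10) fell, and Ncf1 (0.39), Treml2 (0.93), Tgm2 (0.53), Prdm2 (0.15), Zfp846 (0.46), Slc41a3 (0.60) and Adipor2 (0.33) rose.

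In this comparison 41 genes were called, 30 higher and 11 lower, and 1225 had an unadjusted p under 0.05 in edgeR, a count reached in 20 of 100 random splits, the real split included. With only both groups in the fit 27 were called, and the calls of Ldlr (adjusted p = 0.0696), Cirbp (0.0651), Accs (0.134), Arrdc1 (0.0961), Rnf145 (0.230) and Slc38a5 (0.0998) ended. Without a low-count filter Accs (0.0630) and Rnf145 (0.152) were not called, nor were they without the 3 libraries with Xist (0.0611 and 0.0810), where 36 genes were called. Leaving out T733 also left 27. The call of Ldlr ended without W4 or W8 or T583, T635, T726, T727 or T733 (0.0503 to 0.0707), and that of Cirbp without T583 or T733 (0.0503 to 0.0618). Arrdc1 lost its call without W4, W8, W9, W10 or W11 or T583, T591, T726 or T733 (0.0585 to 0.0920), Accs without W3, W9, W10, W11 or W12 or T583, T591, T726, T727, T728 or T733 (0.0507 to 0.0831) and Fbxl12os without W3, W5, W6, W10, W11 or W12 or T583, T591, T635, T726, T727 or T733 (0.0596 to 0.106). Rnf145 lost its call in 19 of the 24 such fits, all but those without W3, W9 or W11 or T589 or T733 (0.0503 to 0.142). Where these calls ended the folds of Ldlr (-0.32 to -0.29), Cirbp (-0.29), Arrdc1 (-0.33 to -0.30), Accs (-0.45 to -0.39), Fbxl12os (0.62 to 0.67) and Rnf145 (-0.15 to -0.12) lay near those of all libraries.

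Of the lists, 17 passed camera between the transgenic knockouts and the wild types, 13 higher and 4 lower, while 0 passed with an estimated correlation and 0 with fry, each with 5 lists at an unadjusted p under 0.05. Interferon response genes were higher in 21 of 26 (median 0.13, adjusted p = 4.48e-05; adjusted p = 0.317 with an estimated correlation), with Ifitm3 at 0.40, Ifit1 at 0.45 and Irf7 at 0.40, none of them called. Glucocorticoid targets were higher in 17 of 22 (9.60e-05; 0.373 with an estimated correlation), with Nfkbia at 0.29, Sgk1 at 0.42 and Lcn2 at 4.01 (SE 0.88, adjusted p = 0.0679). Their score rose by 0.24 in the exact permutation test (adjusted p = 0.0454), with 8 of 8 above the wild-type mean. T726 stood highest, at 4.91 against 4.41 in the next transgenic knockout, and the test was not repeated without T726. Reactive astrocyte genes were higher in 16 of 20 (0.000925; 0.373), with Osmr at 0.47 and Cp at 0.20, and microglia markers in 17 of 20 (0.000807; 0.6248), with Trem2 at 0.22, Ctss at 0.14 and Selplg at -0.20. Cholesterol synthesis genes were lower in 22 of 26 (0.000807; 0.536), with Tm7sf2 at -0.13 and Mvd at -0.12, and fatty acid synthesis genes in 14 of 18 (0.000807; 0.510), with Scd1 at -0.28, Srebf1 at -0.13 and Fasn at -0.13. Ribosomal protein genes (Rpl22 -0.06, Rpl29 -0.09, Rps13 -0.08) were lower in 62 of 74 (0.000807; 0.834) and nuclear oxidative phosphorylation genes in 57 of 74 (0.00702; 0.834). Also higher were heat shock and unfolded protein genes in 26 of 32 (0.000289; 0.680; Hspa1b 0.21, Dnajb1 0.12, Dnajc3 0.13), complement and inflammation in 15 of 20 (0.00133; 0.326), antigen presentation in 13 of 17 (0.00702; 0.510) and disease-associated microglia in 13 of 21 (0.0105; 0.373). The last 5 were striatum markers in 20 of 20 (0.00702; 0.834), endothelial markers in 14 of 18 (0.0265; 0.834), insulin and growth factor signalling in 16 of 20 (0.0265; 0.534), ependyma in 10 of 11 (0.0370; 0.834) and circadian clock genes in 16 of 19 (0.0401; 0.834), and 0 of 22 cell type and region scores passed the exact permutation test, with 1 at p under 0.05 and a smallest adjusted p of 0.957.

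Several of these list calls ended without 1 library, some with a smaller median and some with a median much like that of all libraries. The mean of Lcn2, a secreted iron-binding protein gene induced by inflammation, came largely from T726 at 13.99 CPM, and its log2 fold change was 2.43 without T726 and 1.996 with limma voom. Leaving out T726 ended the calls of antigen presentation (as did W6; median 0.04 to 0.05 from 0.08, adjusted p 0.0558 to 0.0586) and heat shock (0.03 from 0.07, 0.123) and gave calls of Scd1 (0.0466) and Trem2 (0.0334). Ribosomal proteins were lost without T589 (median -0.00 from -0.03, adjusted p = 0.940), striatum without W11 or T635 or T727 (0.09 to 0.17 from 0.21, 0.0966 to 0.654) and endothelial markers without W4 or W6 or T591 (0.08) or T726 (0.03, from 0.10 with all, 0.0848 to 0.430). Oxidative phosphorylation was lost without W11 or W12 or T583, T589 or T635 (-0.02 to -0.00 from -0.02, 0.0510 to 0.912), insulin signalling without W5 or T583, T591 or T726 (0.03 to 0.05 from 0.05, 0.0518 to 0.127) and ependyma without W9, W10, W11 or W12 or T635 or T727 (0.09 to 0.35 from 0.36, lowest without T727, 0.0501 to 0.438). Circadian clock genes were lost without W3, W4, W5, W6 or W12 or T583, T589, T591, T726 or T728 (0.02 to 0.06 from 0.06, lowest without T726, 0.0571 to 0.409). Lcn2 was called without T589 or T728 (0.0437 to 0.0439) and Sgk1 without W11 (0.0477). A cortex layer covariate ended the calls of circadian clock genes (median 0.03 from 0.06, adjusted p = 0.257), endothelial markers (0.07 from 0.10, 0.0744) and insulin signalling (0.05 in both, 0.0718), and a stricter low-count filter that of ependyma (0.15 from 0.36, 0.705).

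Both knockout groups shared 20 called genes against the wild types, 19 higher and 1 lower (Rnf145). They include 9 genes of the chromosome 19 block, with Crybb1, Lyz2, Itgax, Lag3, Olfml3 and Oas2. Without the 3 libraries with Xist 10 genes were shared, all higher, and 10 of the 20 were no longer among them. These were Lag3, Olfml3, Oas2, Adipor2 and Gm13134, with Gfra1, Crybb1, Lyz2, Itgax and Rnf145, whose calls in the knockouts ended (adjusted p = 0.108, 0.128, 0.221, 0.0696 and 0.0696 for the last 5). Because both comparisons use the same wild types, chance alone can add shared calls. Simulated unchanged groups against those wild types gave 0 shared calls in 50 runs, and independent lists of these sizes would share 0.0419 higher and 0.00177 lower genes. Both take genes as independent, so they do not show what structure among the real libraries adds. In the simulated runs at most 2 genes were called higher in the knockouts and 0 in the transgenic knockouts, and at most 1 lower in each. Shared calls could thus hardly arise, and the runs do not measure what the shared wild types add. Splitting the wild types between the comparisons gave 7 to 13 shared higher genes, with a median of 10, and 0 lower genes in 50 splits. These splits left fewer wild types in each comparison, and higher calls in the knockouts fell from 26 to a median of 11.5. In the transgenic knockouts they fell from 30 to a median of 18. The smaller shared count therefore cannot be told apart from the effect of fewer libraries.

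The last comparison set the transgene shift against the knockout and diet shift, to ask whether genes moved back toward wild-type levels with the transgene. Across 18616 genes, which are not independent replicates, the log2 fold changes correlated at -0.60. The knockout libraries enter both with opposite sign, and simulated groups without change gave -0.55. The covariance was -0.0280 against a simulated -0.0170, a difference of -0.0110. With the knockouts split between the comparisons in all 35 ways, the covariance averaged -0.0129 (-0.0165 to -0.00753) and the correlation -0.21 (-0.28 to -0.11), negative in 35 of 35. Permuting library labels over all groups together 10000 times gave a one-sided p of 0.0572 for this mean covariance, which did not pass. The same permutation gave 0.0710 without the 3 libraries with Xist. It takes all groups as alike, so it does not test the transgene alone. The unsplit correlation was weakest without T727 (-0.533), T635 (-0.554), W5 (-0.559) or W4 (-0.560), the libraries lowest on the first principal component. That component followed region markers, and tissue makeup was not separated from this shift. Of the 29 genes called in the knockouts against the wild types, 13 moved the opposite way in the transgenic knockouts and 16 the same way. Without the 3 libraries with Xist these counts were 1 and 10 of the 11 genes called. The 16 hold all 9 genes of the chromosome 19 block and the 10 hold the 8 of them still called, so neighbouring genes weigh on both counts. The knockout libraries enter both comparisons, and no count for groups without change was simulated. These counts therefore do not show whether genes returned toward wild-type levels. Xist was the only gene called in both comparisons with opposite signs.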

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

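The tests for the shared locus on chromosome 2, for pancreas RNA, for a chromosome segment, for DNA near Ldlr, for both effects of the Xist libraries on chromosome 19 and for all explanations of the Xist reads were written only after the results were seen. Those for chance splits and for the other explanations of the chromosome 2 genes were written before the results they measure were seen.

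The first pattern is the rise of Gm14005, Gm14010 and Gm14006 in all AdrTG;LDLRKO HFD mice. It does not come from the libraries with Xist, since 3 of the 3 genes were called without them, nor from a few mice, since 8 of 8 transgenic knockouts lay above every knockout for Gm14005. The 3 genes span 0.380 Mb, but they had been seen as neighbours before this test was written, so it supports no explanation by a locus that differs in cis, which stays open. The test for a change that reaches the protein-coding neighbours found no such gene, with 0 of those within 1 Mb higher at an unadjusted p under 0.05 in edgeR. A small change, or one in neighbours with few reads, could be missed. Whether the transgene itself lies at this locus stays open, since its site and sequence are not given in the sources used here and the counts hold no reads across a junction.

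The second pattern is the block with Pnlip on chromosome 19, which was higher in both knockout groups than in the wild types. Pancreas RNA in the libraries would bring its abundant enzymes, but 15 other acinar genes summed to 3.53 CPM in the knockout groups and 3.86 CPM in the wild types, a change of -4.50% of the rise of Pnlip. Of the 20 genes called in both knockout groups 9 lay in a single 5 Mb window, against at most 4 in 10000 random draws, but the block had been seen before this test was written, so it supports no explanation by a chromosome segment that differs between the stocks, which stays open, while DNA carried along with Ldlr would lie on chromosome 9 and the block lies on chromosome 19. The libraries with Xist do not explain 8 of the 9 genes, which stayed called without them, nor the fold of Gfra1, which was 0.84 (SE 0.15) with them and 0.83 (SE 0.17) without, where less than 0.42 was needed, though its call ended with fewer libraries in the fit (adjusted p = 0.108). Whether diet, the knockout or the breeding of the stock raised these genes stays open, since all differ from the wild types together.

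The third pattern is Xist in K636, K730 and K731, labelled male, where no biological explanation was tested. A female mouse under a male label would lack Y-linked RNA, but the lowest Y-linked gene in the 3 libraries kept 26.6% of the level of the other 4. RNA of both sexes in the same library may remain. Xist was higher where the Y-linked share was lower (54.9%, 38.04% and 31.95% with 210, 365 and 414 CPM), and X-linked Eif2s3x stood at 53.5 to 58.9 CPM against 43.2 to 52.2 CPM in the other 4. The 4 Y-linked genes ranged over 20.4 percentage points in K636, 8.36 in K730 and 12.7 in K731. Only K636 passed the limit of 20 set for a common share, while Eif2s3y alone ran from 15.8 to 28.0 CPM in the other 4. This test therefore cannot decide. Admixed RNA from a transgenic mouse is argued against, since Gm14005 reached at most 16.8% of the level it would need, and so is wild-type RNA in K636 and K731, whose chromosome 19 genes stood at a median of 124% and 117% of the way from the wild types to the other 4 knockouts. In K730 that median was 35.1%, as wild-type RNA could give, but K590 and K592, without high Xist, stood at 72.8% and 66.0%, so that the source stays open.

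Random splits show what other groupings of the same libraries give, and a split that calls many genes points to sample structure. Of 100 splits of the transgenic knockouts and knockouts, the real split included, 2 called at least the 4 genes of the real groups, with 55 in the highest other. For the knockouts and the wild types 1 did, the real split with 29 genes, and the highest other called 0. For the transgenic knockouts and the wild types 3 did, with 41 genes in the real split and 2708 in the highest other. For gene lists, 69 of 100 splits passed at least the 9 lists of the transgenic knockouts against the knockouts (highest other 20), 22 at least the 14 of the knockouts against the wild types (highest other 22) and 12 at least the 17 of the transgenic knockouts against the wild types (highest other 24). With an estimated correlation 7 passed at least the 1 list of the knockouts against the wild types (highest other 4). In the same order 14, 8 and 20 splits gave at least the 1603, 1811 and 1225 genes with an unadjusted p under 0.05 in edgeR (highest other 4259, 3208 and 5326). Counts of passing lists and of unadjusted p of this size thus also arose in other groupings, most often for the lists of the transgenic knockouts against the knockouts. A random split can keep part of the real grouping.

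A library far from the others of its group was found in 35 of 363 groups of values, where chance gives about 1 in 20. The measure is the gap of the highest or lowest library to its nearest neighbour, as a share of the range of the group. T726 stood apart in 9 of them, highest for Ly6a (29.4 against 15.0 CPM, share 0.813), Lcn2 (13.99 against 2.97 CPM, 0.798), Ifitm3 (0.626), Sgk1 (0.594), Hspb1 (0.590), Cp (0.539) and the glucocorticoid target list (0.677), and lowest for Gfra1 (48.3 against 74.1 CPM, 0.551) and the cholesterol synthesis list (0.596). Red blood cell genes were highest in T591 (Hba-a1 0.769, Hba-a2 0.714, Hbb-bs 0.541, the list 0.545) and in W12 (Hba-a1 0.561, Hba-a2 0.643, Hbb-bs 0.523). The choroid plexus list was highest in T727 (0.767), K590 (0.725) and W8 (0.558).

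Among the other knockout libraries, K590 was highest for Ldlr (32.2 against 27.0 CPM, 0.657) and K592 for Ly86 (0.788), K731 was lowest for Itgax (0.622), and K732 was lowest for Fdft1 (0.592) and the complement and inflammation list (0.614). T727 was lowest for Scd1 (0.552). In the wild types, W3 was highest for the complement and inflammation list (0.505) and the fatty acid synthesis list (0.5001), W5 for Ctss (0.550) and Mpeg1 (0.551) and W11 for Gm14005 (0.532), while W11 was lowest for Uty (0.511) and W4 for Rps13 (0.504). A share of 1.00 came from genes read in a single wild type, 1810018F18Rik in W4, Gm14006 in W3 and Pnliprp1 in W5.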

How the results depend on the processing

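The settings without the 3 LDLRKO HFD libraries with Xist and with a cortex layer covariate were chosen after seeing the data, and the others before. Between the transgenic knockouts and the knockouts 4 genes were called, 1 with a stricter low-count filter, which leaves Gm14006, Gm14010 and Xist untested among its 14972 genes, and 3 to 5 in all other settings. Between the knockouts and the wild types 29 were called, 62 with DESeq2, 45 with limma voom and quality weights, 47 at an adjusted p under 0.1 and 11 without the Xist libraries, while other settings gave 23 to 35. Between the transgenic knockouts and the wild types 41 were called, 62 with DESeq2, 94 with 2 surrogate variables and 27 with only both groups in the fit, while other settings gave 30 to 50. For the passing lists (9, 14 and 17 in the same order), an estimated correlation gave 0, 1 and 0 and fry 0, 2 and 0. The cause of these changes was not tested, beyond the looser threshold and the fewer samples named. Leaving out each library in turn called 4 to 4, 23 to 35 and 27 to 41 genes and passed 5 to 11, 11 to 16 and 13 to 20 lists. The correlation of the transgene shift with the knockout and diet shift was -0.605, -0.213 as the mean over 35 splits of the knockouts, -0.373 over the genes called, -0.675 with a stricter filter and -0.712 without the Xist libraries, and -0.652 to -0.533 without each library. The genes called include Xist, at 8.37 in the knockouts against the wild types and -8.68 in the transgenic knockouts against the knockouts. This single gene weighs on the -0.373, and no value without Xist was computed. The process lists that passed the permutation test between the knockouts and the wild types went from 3 to 0 without the Xist libraries, where the 4 knockouts left limit how small an exact p can be.

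For Enho the log2 fold change between the transgenic knockouts and the knockouts was 0.0190 with 2 surrogate variables, 0.0111 with the cortex layer covariate and -0.0468 to 0.0387 without each library. Between the knockouts and the wild types Enho was at -0.0176, -0.00644 and -0.00192 to 0.0226 in these settings, and between the transgenic knockouts and the wild types at -0.00319 with limma voom and -0.0343 to 0.0482 without each library. Gjb1 between the knockouts and the wild types was at -0.0296 with 2 surrogate variables and -0.0127 with the cortex layer covariate, from 0.24, and the covariate also turned the medians of the myelin (-0.0553 from 0.11) and oxidative phosphorylation (-0.00560 from 0.02) lists there. The cause was not tested. The cortex layer median went from 0.12 to 0.0107, which the covariate fixes as the score of that list. Named genes that were called stayed called in 140 of 145, 530 of 574 and 470 of 540 fits in the 3 comparisons, and 0 reversed, while named genes not called gained a call in 1, 12 and 17 fits. No paired analysis was possible because the labels pair no mice. Depth limits what can be said below about 1 CPM, where Gm14010 and Gm14006 had totals of 10 and 4 counts over the 7 knockouts.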

Other observations

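All hypotheses tested here were weighed in the parts above, and the values below were picked after they were seen. The largest axis of variation followed markers of brain regions. The first principal component (21.6% of the variance) correlated over the 24 libraries at r = 0.90 with cortex layer markers, -0.87 with hypothalamus, -0.86 with olfactory bulb and -0.78 with striatum markers, with no test, and the cortex layer score averaged 5.82 ± 0.0854 in the knockouts and 5.64 ± 0.198 in the wild types (exact permutation adjusted p = 0.235).

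Near Ldlr on chromosome 9, 76 other genes within 2 Mb were tested. Of these, 1 was called between the knockouts and the wild types, the zinc finger gene Zfp846 (20581291 to 20605409, log2 fold change 0.37, adjusted p = 0.000461), and 2 between the transgenic knockouts and the wild types, Zfp846 (0.46, adjusted p = 3.93e-06) and Fbxl12os (0.66, adjusted p = 0.0342). The called transcripts with predicted or pseudogene names that were lower in the transgenic knockouts than in the wild types were Pisd-ps1 (14.8 against 23.9 CPM), AC149090.1 (194 against 341 CPM), Gm27032 (10.2 against 13.2 CPM) and Gm26819 (2.01 against 3.10 CPM). Gm42418 averaged 2.07% of counts in the wild types, 1.66% in the knockouts and 2.34% in the transgenic knockouts.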
